A study of Homo sapiens with 12 samples.

How the data were processed

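RNA was sequenced from 12 cultures of H9 human embryonic stem cells, an established cell line, kept in RSeT medium. This medium is meant to hold the naive state of pluripotency, but whether the cells were in that state was not tested here. Each culture had been transfected with oligonucleotides at 25 nM from 1 of 3 sets. ASO-Ctr is an antisense set with no intended target. ASO-L1 is antisense to the RNA of LINE1 (L1), a family of mobile genetic elements, and SO-L1 is the matching set in the sense orientation. After transfection every culture received 10 nM DZNep, which lowers histone methylation by inhibiting S-adenosylhomocysteine hydrolase, and 5 nM TSA, a histone deacetylase inhibitor. Harvest was at 48 h, without sorting of cells. Per the labels, trans-ISRIB, emricasan and Y-27632, which act on the integrated stress response, on caspases and on ROCK, were taken out at 24 h in all groups. Each of the 3 groups has 4 libraries with the numbers 1 to 4, made as stranded poly(A) RNA libraries.

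The submitters' notes name Trim Galore 0.4.0, TopHat2 2.0.13 and featureCounts from Subread 1.5.0, with genome build hg19. The deposited main table holds raw counts per gene symbol. Its name bears the tag rmDup, for duplicates removed, and does not tell whether these were reads or gene rows. Its 53712 named genes hold whole numbers that sum to between 20367989 and 32180891 per library. A further deposited table holds log2 normalised values that its name calls batch corrected; the batches and the method are not given. The authors' result table for ASO-L1 against SO-L1 gives log2 fold changes, each with a p-value and an adjusted p-value. It also holds deposited moderated t and B scores, which were not used here. Gene symbols that read as dates, 26 of them, were kept as they stand. No counts for L1 elements are in the table, so the level of L1 RNA was not analysed here.

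Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (least count 10, least total count 15), which left 17228 genes. TMM factors were used, and a robust quasi-likelihood model was fitted to all 12 libraries with a mean per group. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 in the edgeR quasi-likelihood F test, which is two-sided. The SE of a log2 fold change is its size divided by the square root of F. Counts were scaled by effective library size to CPM, and CPM means are over 4 libraries with their SD. The depth limits the precision: 3 counts in a whole group correspond to 0.0302 CPM in ASO-Ctr, and such floors cover counting error only, since PCR copies are not independent molecules.

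Before the data were examined, 25 gene lists were written. They cover 8-cell stage genes; naive, primed and core pluripotency; PRC2 subunits and developmental regulators repressed by PRC2; nucleolus and ribosome biogenesis; p53 targets; ATF4 and unfolded protein response; interferon response; cholesterol synthesis; glycolysis and hypoxia; cell cycle and proliferation; and immediate early genes. The others are L1 and heterochromatin silencing factors, mitochondrially encoded RNAs, trophectoderm and amnion markers, primitive endoderm markers, germ layer markers and fibroblast and feeder markers. Lists by name pattern are cytosolic ribosomal protein genes, replication-dependent histone genes, ZNF zinc finger genes, small nucleolar RNA host genes, and genes whose symbols begin like those of repeats. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2. The inter-gene correlation was preset at 0.01, and the test was run again with an estimated correlation. Adjustment was over the 25 lists of a comparison. The fry test was also run; it asks whether the genes of a list move on balance 1 way and does not compare them with other genes.

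The named genes follow a rule set before the data were examined. Per comparison it takes the 10 higher and the 10 lower genes with the smallest p, among genes that moved the same way in all 4 same-number pairs and have a mean log2 CPM above 1. If fewer than 5 passed in either direction, the rule was applied to the fit with the library number as a block. From each list it takes up to 4 members past the threshold, or 2 members with the highest mean where none passed. In the overlap of both ASO-L1 comparisons it takes 5 per direction. The rule also names ZSCAN4, LEUTX, TPRX1, DUXA, KLF17, DPPA3, POU5F1, NANOG, SOX2, EZH2, SUZ12, EED, NCL and TRIM28. Each of these is reported for ASO-L1 against ASO-Ctr, LEUTX and DUXA by counts only, and a part of them for the other comparisons. Not every gene that the rule takes from a list is printed. Genes named outside the rule are marked as such.

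No label says what libraries of the same number share. Once the group means were taken out, libraries of the same number in different groups correlated across genes at r from 0.450 to 0.561, and so did numbers 1 with 2 and 3 with 4, at r from 0.455 to 0.543. Between these sets of numbers r lay between -0.530 and -0.426. Of 24 best matches between a library and another group, 15 had the same number. The fit with the number as a block is therefore given beside calls that it changes, and beside the list counts of ASO-L1 against ASO-Ctr where these move. Values within numbers 1 and 2 and within numbers 3 and 4 are given for the counts of changed genes, and for named genes and lists of ASO-L1 against ASO-Ctr whose change differed between them. That grouping was found in the data. The median squared difference between 2 libraries of a group, over that expected from counting alone, was 1.38 to 2.25 within these sets. Across the sets it was 5.99 to 7.44. The SEs, p-values and permutation tests treat the 4 libraries of a group as independent. If libraries of a set came from 1 experiment, n = 4 overstates the replication, which no label settles.

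The tests were checked on simulated data in which 200 genes were changed and the rest were not. For ASO-L1 against ASO-Ctr the model without a block recovered 33 of 66 genes changed 1.5-fold, 46 of 66 changed 2-fold and 58 of 65 changed 4-fold, with 0 false calls. With the block it recovered 52, 60 and 65 of these, and 7.33% of its calls were false. For ASO-L1 against SO-L1 the model without a block recovered 32 of 66, 53 of 66 and 61 of 66, and for SO-L1 against ASO-Ctr 41 of 66, 53 of 64 and 63 of 64. The list test called a list of 20 genes changed 1.5-fold in 10 of 10 simulations, and 0 of 240 unchanged lists. The simulated lists held random genes with noise independent between genes. The 0 therefore does not cover lists whose genes vary together, such as the 8-cell stage list (estimated correlation 0.331).

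Alternatives set before the data were examined were the block, RLE size factors, library sizes alone, DESeq2 1.42.0, limma-voom, other count filters, fits of the compared groups alone, a test against a fold of 1.5, the deposited log2 values, and leaving out each library. A covariate for the set of numbers and fits within each set were added after seeing the data. Gene spans and exonic lengths were taken by symbol from GENCODE 29 (build GRCh38) and were found for 89.2% of the tested genes. Sets of genes were compared with 1000 draws of tested genes matched on mean expression.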

Results

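Gene expression was measured by RNA sequencing in 12 cultures of H9 cells in RSeT medium, 4 each with ASO-Ctr, SO-L1 and ASO-L1 oligos. Total counts lay between 20367989 (SO-L1 1) and 32180891 (ASO-L1 2) per library. Mitochondrially encoded RNAs took 7.14% ± 1.60, 7.28% ± 0.644 and 7.10% ± 1.19 of the counts. The first principal component held 40.6% and the second 28.4% of the variance, and the libraries separated both by ASO-L1 against the rest and by numbers 1 and 2 against numbers 3 and 4. CPM values below are means ± SD (n = 4), log2 fold changes are ± SE, and each gene said to rise or fall did so in all 4 same-number pairs.

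**Figure D1:**
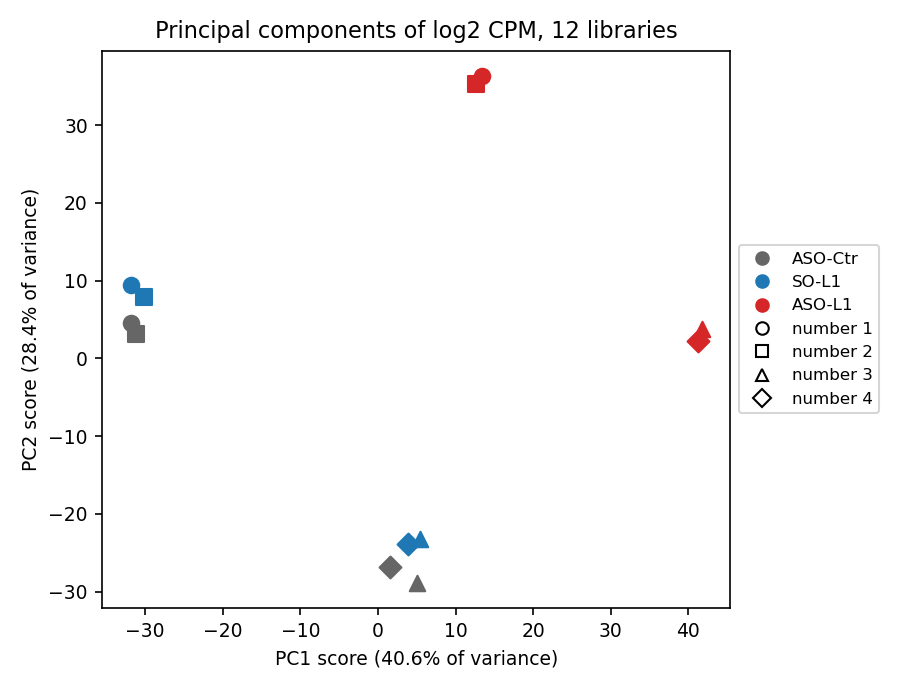
Scores of the 12 libraries on the first (x axis, 40.6% of the variance) and second (y axis, 28.4%) principal components of log2 CPM. Colours give the oligo group and symbols the library number; ASO-L1 lies apart from both other groups within numbers 1 and 2 and within numbers 3 and 4.

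ASO-L1 against ASO-Ctr asks how targeting L1 RNA alters expression in these cells, and the series states an interest in genes of the 8-cell stage. Of 17228 genes tested, 2007 were higher and 1840 lower in ASO-L1. Most changes were small, with a median of 1.34-fold for higher and 1.27-fold for lower genes, and 380 genes rose and 38 fell by at least 2-fold. The genes with the smallest p included the stress and signalling genes RHOB, a small GTPase, which rose from 86.0 ± 5.90 to 256 ± 3.25 CPM (log2 change 1.58 ± 0.05, adjusted p = 1.66e-09). Another was ATF5, a transcription factor of the integrated stress response, which rose from 24.9 ± 1.80 to 95.5 ± 1.27 CPM (1.94 ± 0.07). ECM1, a secreted matrix protein, rose from 1.62 ± 0.126 to 21.9 ± 1.51 CPM (3.75 ± 0.17). FXYD4, a regulator of the sodium pump, rose from 0.444 ± 0.139 to 7.84 ± 0.584 CPM (4.12 ± 0.19). LYPD3 (6.21 ± 0.309 to 24.8 ± 1.95 CPM), TSC22D3 (1.28 ± 0.05) and C6orf48 (0.92 ± 0.04) were also among the first 10. The lower genes with the smallest p were SEMA6A, a semaphorin (359 ± 11.3 to 235 ± 1.82 CPM, -0.61 ± 0.03), ALDH7A1, an aldehyde dehydrogenase (-0.61 ± 0.04), FOCAD (-0.75 ± 0.05) and LRRN1 (-0.44 ± 0.03). They were followed by PCSK5 (-0.69 ± 0.05), HEPH (-0.69 ± 0.05), RTCA (-0.58 ± 0.04), CACHD1 (-0.66 ± 0.05), SESTD1 (-0.60 ± 0.05) and N4BP1 (-0.52 ± 0.04).

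Of 46 genes of the 8-cell stage in the table, 9 were tested, of which 5 rose with ASO-L1, 0 fell and 4 did not pass (6 higher and 0 lower adjusted over the list alone, 7 and 0 with the block). FAM151A went from 0.360 ± 0.159 to 2.53 ± 1.39 CPM (2.78 ± 0.42, adjusted p = 4.56e-04). ZSCAN4, a zinc finger gene of embryonic genome activation, rose from 0.305 ± 0.0290 to 1.20 ± 0.637 CPM (1.95 ± 0.40, adjusted p = 0.00370). The homeobox gene TPRX1 rose from 1.33 ± 0.656 to 5.52 ± 3.57 CPM (2.02 ± 0.49, adjusted p = 0.00928). The phosphate transporter SLC34A2 rose from 0.977 ± 0.497 to 4.258 ± 3.004 CPM (2.11 ± 0.55, adjusted p = 0.0152). ZNF280A, named after its values were seen, was the remaining gene that rose (2.61 ± 0.68, adjusted p = 0.0153). CCNA1, a cyclin, stood at 33.9 ± 15.8 and 83.8 ± 46.5 CPM (1.31 ± 0.46) with an adjusted p of 0.0656, and 1.39e-12 with the block. KLF17, at 0.295 to 0.517 CPM in the ASO-Ctr libraries, had 0.82 ± 0.48 (adjusted p = 0.258, and 0.0466 with the block). It had -0.12 in numbers 1 and 2 and 1.26 in numbers 3 and 4, a difference that did not pass (interaction test, adjusted p = 0.496). CCNJ (-0.09 ± 0.05, adjusted p = 0.300) and ZNF296 (-0.07, adjusted p = 0.879, outside the rule) did not pass. The list median was 1.95 over the 9 tested genes (camera adjusted p = 0.0182, and adjusted p = 0.299 with an estimated correlation). The fry test, which was run on every list and is printed for this list alone, gave an adjusted p of 0.00735. With no filter on low counts the median was 1.51 over 29 genes. Over the 9 genes it was 1.10 in numbers 1 and 2 and 2.28 in numbers 3 and 4. This difference had an adjusted p of 1.69e-04 in camera and 0.149 with an estimated correlation. ZSCAN4 had 1.03 and 2.58 in these sets, a difference that did not pass (adjusted p = 0.338), and in numbers 1 and 2 alone its adjusted p was 0.0662. With no filter on low counts, TPRX1 and SLC34A2 no longer passed (adjusted p = 0.0533 and 0.0776), nor did SLC34A2 in limma-voom (0.0577).

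A further 37 of the 8-cell stage genes had too few counts to test, and 17 of them had 0 counts in all libraries. The other untested genes together held 60 counts in ASO-Ctr, 84 in SO-L1 and 301 in ASO-L1. Scaled to CPM by total counts alone this was 0.609 ± 0.192 in ASO-Ctr and 2.81 ± 1.97 in ASO-L1 (exact permutation p = 0.0286, two-sided, the smallest that 70 splits allow; adjusted p = 0.0857 over 3 comparisons). In SO-L1 it was 0.835 ± 0.361 (0.344, 0.822, 1.19 and 0.982 by number). ASO-L1 was higher in all 4 same-number pairs, but the unpaired exact permutation test did not pass (p = 0.0857, adjusted p = 0.129). The ASO-L1 libraries held 1.17 and 1.06 CPM of them in numbers 1 and 2, and 4.62 and 4.41 in numbers 3 and 4, against 0.534, 0.441, 0.885 and 0.576 in ASO-Ctr. KDM4E, a histone demethylase gene, made up 101 of the counts in ASO-L1 against 5 in ASO-Ctr, and RFPL2 76 against 9; both were named after their values were seen. LEUTX had 0 counts in ASO-Ctr, which allows up to 0.0302 CPM, and 3 in ASO-L1, and DUXA had 1 and 2, so neither could be told from its background at this depth.

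**Figure D2:**
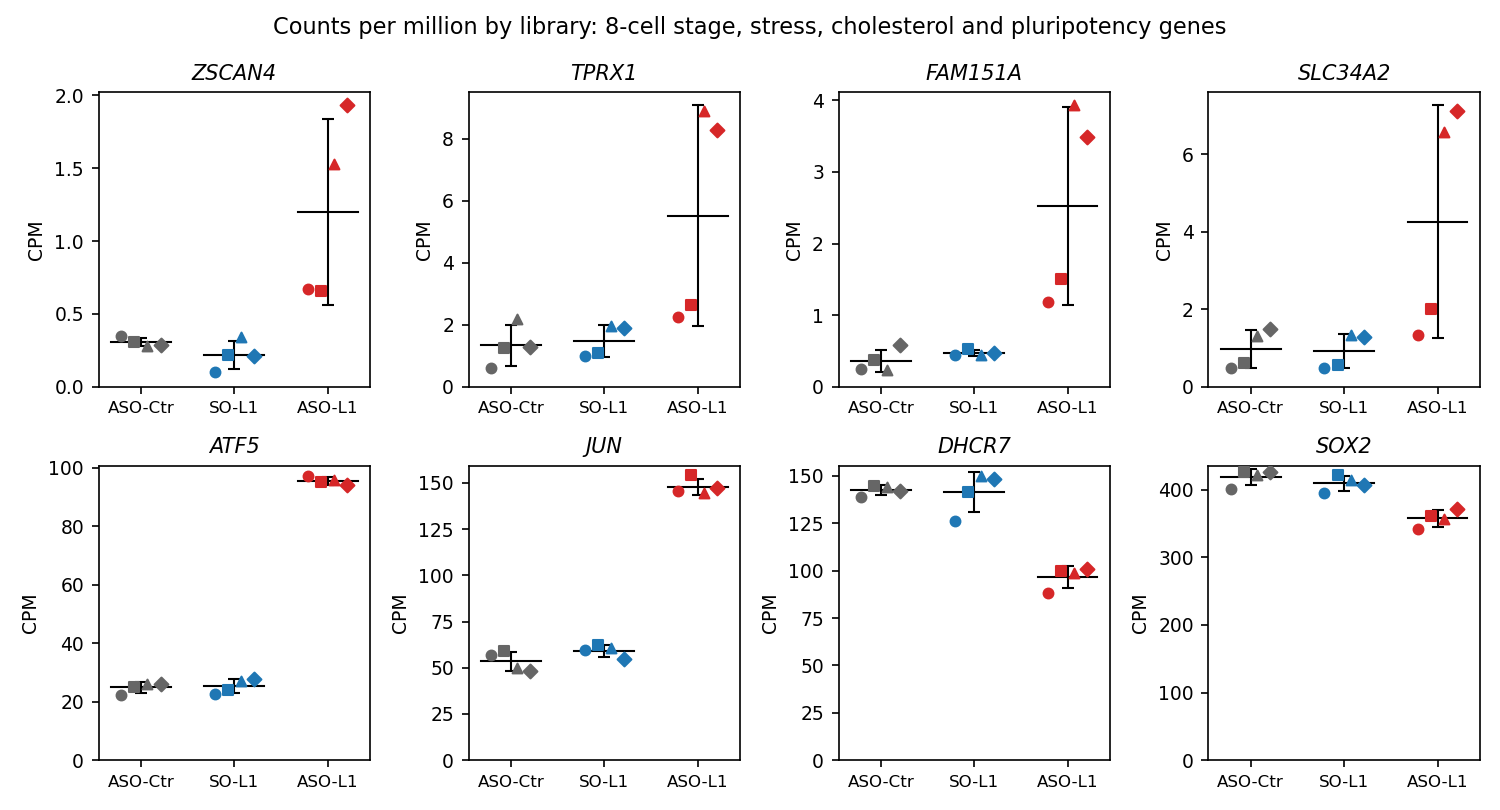
Counts scaled to CPM (y axes, linear from 0) of 8 genes in each library, by oligo group (x axes). Points are libraries with a symbol per number as in the plot of principal components, horizontal bars are means and error bars are SD (n = 4); ATF5 is near 95.5 CPM in all ASO-L1 libraries, while the 8-cell stage genes in ASO-L1 are higher in numbers 3 and 4 than in numbers 1 and 2.

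Immediate early genes respond within minutes to growth factors and stress. Of 24 tested, 15 rose and 0 fell (21 and 1 adjusted over the list alone, 22 and 1 with the block), with a median of 0.68 (camera adjusted p = 6.31e-13, and adjusted p = 0.00294 with an estimated correlation). JUN went from 53.5 ± 5.21 to 148 ± 4.36 CPM (1.47 ± 0.07), KLF2 rose by 2.29 ± 0.10, ATF3 by 1.495 ± 0.07 and KLF6 by 1.01 ± 0.08 on the log2 scale. Of 38 genes of the ATF4 and unfolded protein response, 14 rose and 4 fell (16 and 7 with the block), with a median of 0.05 and a mean of 0.31 (camera adjusted p = 0.00285, and adjusted p = 0.152 with an estimated correlation). Besides ATF5 and ATF3, the members that rose included PPP1R15A, a phosphatase subunit that reverses eIF2 alpha phosphorylation (1.41 ± 0.06), and TRIB3 (1.27 ± 0.11). The chaperone HSP90B1 fell by 0.34 ± 0.05, and HSPA5 stood at -0.03 ± 0.09 (adjusted p = 0.863). Of 30 p53 targets 9 rose and 3 fell, against 11 and 10 with the block, with a median of -0.05 against an upward direction in camera (adjusted p = 0.499). Among them AEN (0.42 ± 0.04) and PLK3 (0.83 ± 0.11) rose and the death receptor gene TNFRSF10B fell (-0.63 ± 0.08). Of 41 interferon response genes 8 rose and 1 fell (16 and 7 with the block; median 0.16, camera adjusted p = 0.0217, and adjusted p = 0.156 with an estimated correlation; 0.0575 with the block). ISG20 (1.86 ± 0.13), IFI27 (2.69 ± 0.22), ISG15 (0.83 ± 0.09) and IRF7 (0.59 ± 0.10) were among the higher ones.

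In the cholesterol synthesis list 14 of 25 genes fell and 0 rose (15 and 0 adjusted over the list alone, 21 and 0 with the block; median -0.23, camera adjusted p = 8.53e-07, and adjusted p = 0.0965 with an estimated correlation). DHCR7, the last enzyme of the pathway, fell from 142 ± 2.58 to 96.8 ± 5.91 CPM (-0.56 ± 0.06), with FDFT1 (-0.47 ± 0.05) and the regulator SREBF2 (-0.26 ± 0.04). Of 20 core pluripotency genes 8 fell and 0 rose (10 and 0 adjusted over the list alone, 16 lower and 1 higher with the block; median -0.14, camera adjusted p = 5.44e-04, and adjusted p = 0.0965 with an estimated correlation). These were small changes: DNMT3B -0.34 ± 0.03, GDF3 -0.39 ± 0.05, TERF1 -0.37 ± 0.05, SOX2 -0.23 ± 0.04 and POU5F1 -0.18 ± 0.04. NANOG stood at -0.09 ± 0.06 (adjusted p = 0.331, and 0.0183 with the block). Of 26 naive pluripotency genes 9 rose and 1 fell, with 9 and 5 adjusted over the list alone and 13 and 9 with the block (median 0.11, camera adjusted p = 0.156). KLF4 (0.88 ± 0.10), TFCP2L1 (0.74 ± 0.08) and UPP1 (0.58 ± 0.06) rose, while DPPA3 stood at 0.07 ± 0.28 (adjusted p = 0.902), with opposite signs in numbers 1 and 2 (-0.11) and in numbers 3 and 4 (0.35; adjusted p of the difference 3.7e-04). TFCP2L1 rose by 0.93 in numbers 1 and 2 and by 0.53 in numbers 3 and 4 (adjusted p of the difference 0.0165). Of 25 primed pluripotency genes, 6 higher and 10 lower with the block, 1 rose, ZIC2 (0.76 ± 0.18), and 3 fell, among them DNMT3B and TCF7L1 (-0.36 ± 0.08; camera adjusted p = 0.499).

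PRC2, the Polycomb complex that methylates lysine 27 of histone H3, is named in the series title. Of 13 subunit genes, 1 higher and 6 lower with the block, PHF1 rose (0.34 ± 0.06) and JARID2 fell (-0.16 ± 0.04; camera adjusted p = 0.617). EZH2, the catalytic subunit, stood at 101 ± 16.7 CPM in ASO-Ctr and 80.6 ± 14.2 in ASO-L1 (-0.32 ± 0.15, adjusted p = 0.156, and 4.46e-10 with the block), SUZ12 at 0.02 ± 0.05 (adjusted p = 0.854) and EED at 0.08 ± 0.06 (adjusted p = 0.399). Of 28 tested developmental regulators repressed by PRC2, 9 rose and 2 fell (11 and 4 with the block; median 0.27, camera adjusted p = 0.0217, and adjusted p = 0.229 with an estimated correlation; 0.0644 with the block). TWIST1 went from 3.25 ± 0.813 to 12.4 ± 0.859 CPM (1.93 ± 0.14), and ALX1 (0.97 ± 0.13) and SOX18 (2.25 ± 0.30) rose, while SOX21 fell (-0.60 ± 0.09). Nucleolar and ribosome biogenesis genes, tied to the nucleolar theme of the title, gave 13 higher and 5 lower of 73, with 14 and 5 adjusted over the list alone and 35 and 7 with the block (median 0.09, camera adjusted p = 0.0217, and adjusted p = 0.7998 with an estimated correlation). RRN3, an initiation factor of RNA polymerase I, rose (0.37 ± 0.04), HEATR1 (-0.34 ± 0.04), DDX21 (-0.20 ± 0.03) and UTP20 (-0.31 ± 0.06) fell, and NCL stood at 0.04 ± 0.05 (adjusted p = 0.635). Small nucleolar RNA host genes rose in 10 of 13 cases and fell in 1 (12 and 1 adjusted over the list alone and with the block; median 0.50, camera adjusted p = 8.41e-06, and adjusted p = 0.0646 with an estimated correlation). SNHG1 rose from 221 ± 15.3 to 356 ± 25.8 CPM (0.69 ± 0.07), with SNHG8 (0.69 ± 0.08), SNHG7 (0.68 ± 0.12) and SNHG5 (0.29 ± 0.05). SNHG14 fell by 0.26 ± 0.06.

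Markers of other cell types moved in part. Of 14 trophectoderm and amnion markers 8 rose and 0 fell (median 0.48, camera adjusted p = 5.44e-04, and adjusted p = 0.0965 with an estimated correlation), among them KRT18 (0.53 ± 0.07), KRT8 (0.63 ± 0.09), GATA2 (1.03 ± 0.18) and DLX3 (2.62 ± 0.40). Of 18 fibroblast and feeder markers 9 rose and 0 fell (10 and 3 with the block; median 0.33, camera adjusted p = 5.44e-04, and adjusted p = 0.229 with an estimated correlation). VIM went from 116 ± 9.30 to 294 ± 47.4 CPM (1.34 ± 0.10), SPARC rose by 0.63 ± 0.07 and S100A4 by 1.45 ± 0.17. Of 11 germ layer markers 4 rose and 1 fell (6 and 1 with the block; median 0.24, camera adjusted p = 0.0217, and adjusted p = 0.0965 with an estimated correlation). CER1, a secreted Nodal antagonist, went from 13.8 ± 4.65 to 87.0 ± 26.3 CPM (2.65 ± 0.30), with MIXL1 (0.61 ± 0.11), NES (0.45 ± 0.07) and WNT3 (0.24 ± 0.07). The WNT3 call was lost without ASO-L1 1, 2 or 3 (adjusted p = 0.0641, 0.0589 and 0.0605), ASO-Ctr 2 (0.0802) or ASO-Ctr 3 (0.0742). Of 14 primitive endoderm markers, 2 higher and 5 lower with the block, GATA6 rose (3.58 ± 0.60) from 0.0905 ± 0.127 to 1.14 ± 0.368 CPM, and PDGFRA (-0.70 ± 0.08) and COL4A2 (-0.40 ± 0.08) fell. The median was -0.17 and the mean 0.16 (camera adjusted p = 0.475).

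The remaining lists were not called by camera, except the ZNF zinc finger genes. Of 491 of these, 76 rose and 26 fell (74 and 25 adjusted over the list alone, 149 and 61 with the block; median 0.05, adjusted p = 0.0256, and adjusted p = 0.0965 with an estimated correlation), with ZNF436 (1.47 ± 0.15), ZNF823 (0.95 ± 0.08) and ZNF487 (1.09 ± 0.14) higher and ZNF514 (-0.55 ± 0.07) lower. Of 42 L1 and heterochromatin silencing factors 0 rose and 9 fell (5 higher and 17 lower with the block; adjusted p = 0.119), among them SAMHD1 (-0.39 ± 0.09), a restriction factor of L1, PIWIL2 (-0.40 ± 0.11) and LIN28A (-0.18 ± 0.05). Both lost their call without ASO-Ctr 2, ASO-L1 3 or ASO-L1 4, with adjusted p of 0.0622, 0.0524 and 0.0553 for PIWIL2 and of 0.0555, 0.0583 and 0.0657 for LIN28A. TRIM28 stood at 0.10 ± 0.03 (adjusted p = 0.0526, and 0.00375 with the block). Of 34 glycolysis and hypoxia genes, 5 higher and 16 lower with the block, NDRG1 (1.46 ± 0.13) and ENO2 (0.43 ± 0.13) rose and PFKP (-0.29 ± 0.03) fell (adjusted p = 0.716). ENO2 lost its call without ASO-L1 1, 2 or 3 (adjusted p = 0.105, 0.111 and 0.0545), ASO-Ctr 3 (0.112) or ASO-Ctr 4 (0.102). Of 42 cell cycle genes 7 rose and 4 fell (16 and 12 with the block; adjusted p = 0.499), with CDC20 (0.39 ± 0.07) and MYBL2 (0.40 ± 0.08) higher and KIF11 (-0.17 ± 0.04) and RRM1 (-0.30 ± 0.06) lower. The 80 ribosomal protein genes had a median of 0.03 (adjusted p = 0.237), and 0 passed adjusted over the list alone; with the block 15 were higher and 4 lower. None of 24 replication-dependent histone genes (adjusted p = 0.750) and none of 13 mitochondrially encoded RNAs (adjusted p = 0.962) passed, in edgeR without and 3 and 0 of them with the block. HIST1H2BK stood at -0.06 ± 0.19, HIST1H2AC at -0.05 ± 0.08, MT-CO1 at 0.00 ± 0.15 and MT-ND4 at -0.03 ± 0.16. Of 10 genes with repeat-like symbols, none of which counts L1 elements, L1CAM (0.82 ± 0.10), a cell adhesion gene, and ERVV-2 (1.66 ± 0.28), an endogenous retroviral gene, rose (3 higher and 2 lower with the block; median -0.05, mean 0.19, adjusted p = 0.499). L1TD1 stood at -0.11 ± 0.08 (adjusted p = 0.356, and 0.00137 with the block).

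**Figure D3:**
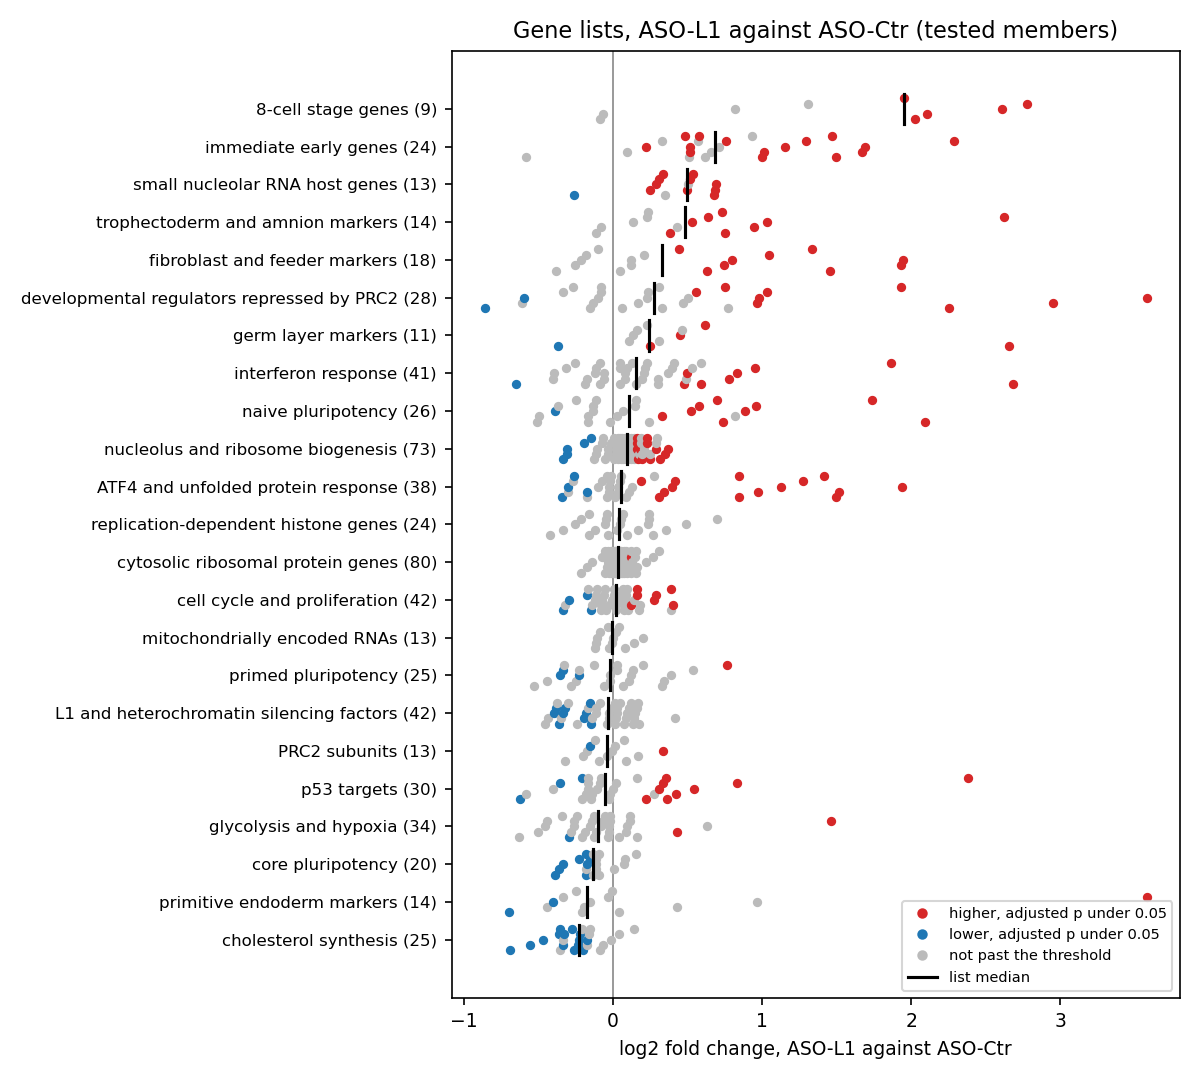
Log2 fold change in ASO-L1 against ASO-Ctr (x axis) of each tested member of the gene lists (y axis, number tested in brackets); the ZNF and repeat-like lists are left out. Points are genes, coloured by call, and black bars are list medians, which run from -0.23 for cholesterol synthesis to 1.95 for 8-cell stage genes.

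The counts of changed genes depended on how library numbers were treated. With the number as a block, 3869 genes were higher and 3878 lower in ASO-L1 than in ASO-Ctr, 3845 of them called without it too; the fits within numbers 1 and 2 and within numbers 3 and 4 called 6045 and 6103 genes. The change differed between the sets for 134 genes by an interaction test. Among genes named above, KRT18 (0.66 in numbers 1 and 2, 0.40 in numbers 3 and 4), SNHG7 (0.90 and 0.50), NES (0.56 and 0.33) and L1CAM (1.01 and 0.63) differed in size, with adjusted p of 0.0205, 0.0350, 0.0394 and 0.0439. By camera the ATF4 (medians 0.00 and 0.17, adjusted p = 3.22e-04), cholesterol (-0.27 and -0.18, 8.65e-07), glycolysis (-0.16 and -0.03, 3.46e-06) and fibroblast lists (0.49 and 0.32, 0.00280) differed as well, none of them with an estimated correlation (smallest adjusted p = 0.149). Against a fold of 1.5, 240 genes were higher and 5 lower.

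ASO-L1 against SO-L1 asks how the antisense set differs from the sense set of L1 oligos. Of the 17228 genes, 1837 were higher and 1660 lower in ASO-L1, 321 and 32 of them by at least 2-fold. RHOB (1.41 ± 0.05), ATF5 (1.91 ± 0.07), C6orf48 (0.95 ± 0.04), ECM1 (3.75 ± 0.17), and LYPD3 (1.69 ± 0.08) led the higher genes. PPP1R15A (1.16 ± 0.06), JUN (1.32 ± 0.07), FXYD4 (3.48 ± 0.18), TSC22D3 (1.06 ± 0.05) and KLF2 (1.97 ± 0.10) came next by p. Lower were ALDH7A1 (-0.62 ± 0.04), SEMA6A (-0.56 ± 0.03), LRRN1 (-0.43 ± 0.03), RTCA (-0.61 ± 0.04), and TMEM87A (-0.62 ± 0.04). Then came FOCAD (-0.63 ± 0.05), RAB15, a small GTPase (-0.47 ± 0.03), the splicing factor SYF2 (-0.55 ± 0.04), N4BP1 (-0.52 ± 0.04) and SESTD1 (-0.58 ± 0.05). Of the 9 tested 8-cell stage genes 5 rose and 0 fell (6 and 0 adjusted over the list alone, 6 and 1 with the block), with FAM151A at 2.42 ± 0.41, and ZSCAN4 at 2.37 ± 0.42. SLC34A2 was at 2.17 ± 0.56, TPRX1 at 1.86 ± 0.48 and ZNF280A, again outside the rule, at 2.63 ± 0.68. The list median was 1.86 (camera adjusted p = 0.00807, and adjusted p = 0.265 with an estimated correlation), 1.23 in numbers 1 and 2 and 2.15 in numbers 3 and 4. TPRX1 lost its call without ASO-L1 3 (1.53, adjusted p = 0.0516), in limma-voom (0.0579) and with no count filter (0.0789), as did SLC34A2 in limma-voom (0.0625) and with no count filter (0.0770).

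The other lists moved much as against ASO-Ctr, with 13 of 25 called by camera. Of 24 immediate early genes 18 rose and 0 fell (median 0.81, adjusted p = 5.06e-14, and adjusted p = 0.00215 with an estimated correlation). Of 13 small nucleolar RNA host genes 12 rose and 1 fell (median 0.44, adjusted p = 1.35e-06, and adjusted p = 0.0432 with an estimated correlation, though 0.213 with both this and the block). These were the lists whose call held with an estimated correlation, and against ASO-Ctr only the immediate early genes did. Of 25 cholesterol genes 13 fell and 0 rose (20 and 0 with the block; median -0.22, adjusted p = 1.00e-06, and adjusted p = 0.122 with an estimated correlation). Of 20 core pluripotency genes 5 fell (12 with the block; adjusted p = 0.00302, and adjusted p = 0.122 with an estimated correlation). SOX2 was at -0.20 ± 0.04 and POU5F1 at -0.13 ± 0.04, whose call was lost without SO-L1 1, 2 or 3 (adjusted p = 0.0555, 0.0910 and 0.0591) or ASO-L1 1, 3 or 4 (0.0517, 0.0952 and 0.0806). NANOG (-0.06 ± 0.06, adjusted p = 0.560), EZH2 (-0.28 ± 0.15, adjusted p = 0.231, and 1.71e-08 with the block) and TRIM28 (0.09 ± 0.03, adjusted p = 0.0658, and 0.0058 with the block) did not pass. Of 80 ribosomal protein genes 4 rose, none adjusted over the list alone (21 higher and 3 lower with the block; median 0.05, adjusted p = 0.0355, and adjusted p = 0.866 with an estimated correlation). The interferon list was not called (adjusted p = 0.0617). Median, mean and camera direction differed in sign for the primed, p53, primitive endoderm, histone and repeat-like lists, none of them called. With the block the calls of the PRC2-repressed regulators (adjusted p = 0.0399 to 0.134) and of the ATF4 list (0.00715 to 0.0638) ended, and glycolysis and hypoxia genes were called lower (0.00729, and adjusted p = 0.518 with an estimated correlation). The block gave 3727 higher and 3742 lower genes, and the fits within the sets of numbers 5863 and 5861. In the authors' own table of this comparison 5371 of 21414 genes had an adjusted p under 0.05, 2764 higher and 2607 lower. Of these, 3488 were called in the same direction there and here and 0 in opposite directions.

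SO-L1 against ASO-Ctr compares the control sets. In edgeR 5 genes passed, all lower in SO-L1, with 527 genes at an unadjusted p under 0.05. They were MYO6, an unconventional myosin (126 ± 2.82 to 80.4 ± 1.92 CPM, -0.65 ± 0.04, adjusted p = 2.96e-05), EDA, ectodysplasin (-0.76 ± 0.07), BBS9, a BBSome subunit (-0.67 ± 0.07), SNAP23, a SNARE protein (-0.46 ± 0.05), and the netrin receptor gene NEO1 (-0.35 ± 0.04, named after its values were seen). MYO6 and SNAP23 were higher in ASO-L1 than in SO-L1, by 0.44 ± 0.04 and 0.35 ± 0.05. In ASO-L1 against ASO-Ctr, MYO6, BBS9 and EDA were also called lower without the block, while SNAP23 was not called. DESeq2 called 46 genes and limma-voom 6. With the block 73 genes were higher and 170 lower, and the fits within numbers 1 and 2 and within numbers 3 and 4 called 124 and 201. In the blocked fit the lower genes with the smallest p after MYO6, BBS9, EDA and SNAP23 were TUSC3 (-0.38), NBAS (-0.43), GAB1 (-0.49), MMP16 (-0.69), ZNF638 (-0.30) and UACA (-0.38). The higher ones were PTPRN (0.28), PPP2R3A (0.41), MOBP (1.09), SPP1 (0.28), ACSL3 (0.19), CACNA2D1 (0.26), TINCR (0.67), MAP1A (0.59), WARS (0.18) and ANXA2 (0.17). Among these further genes, TUSC3, NBAS and ZNF638 were also called lower in ASO-L1 than in ASO-Ctr without the block. SPP1, TINCR, MAP1A and ANXA2 were also called higher there, and the others were not called. No list had a member past the threshold without the block, and camera called 0 of 25 lists. Median, mean and camera direction differed in sign for the 8-cell, immediate early, germ layer, fibroblast, ZNF and repeat-like lists. ZSCAN4 (-0.42 ± 0.52), TPRX1 (0.16 ± 0.54) and CCNA1 (0.11 ± 0.47) did not pass, nor did POU5F1, NANOG, SOX2, EZH2, SUZ12, EED, NCL and TRIM28, each within 0.05 of 0. With the block camera called 6 lists, of which none passed with an estimated correlation (smallest adjusted p = 0.297): ATF4 (adjusted p = 9.37e-04) and glycolysis (0.00484) upward, and primed pluripotency (9.37e-04), core pluripotency (0.0440), nucleolus (0.0234) and primitive endoderm (0.0234) downward.

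Both ASO-L1 comparisons share the ASO-L1 libraries, which alone makes their changes correlate. Across genes, which are not independent replicates, r was 0.920, against a mean of 0.472 and at most 0.486 in 20 simulations without any effect. Higher in both were 1592 genes and lower in both 1390, where independent lists would share 214.0 and 177. These comparisons are not independent. The simulations gave 0 shared calls, but without any effect there is little to call. Neither value therefore measures how much overlap the shared libraries add. With disjoint ASO-L1 libraries in each comparison r was 0.821 or 0.825, and 749 or 840 genes were called the same way. RHOB, ATF5, C6orf48, ECM1 and LYPD3 led the genes higher in both, and ALDH7A1, SEMA6A, LRRN1, FOCAD and RTCA those lower in both. With the block 6270 genes were changed the same way in both.

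Long genes were over-represented among the genes lower in ASO-L1, although 142 of those lower against ASO-Ctr spanned under 10 kb. The 1390 genes lower in both comparisons had a median span of 97.2 kb and the 1592 higher ones 21.1 kb, against 30.8 kb for all tested genes. Of 672 genes over 300 kb, 299 (44.5%) were lower and 6 higher in ASO-L1 than in ASO-Ctr, with a median change of -0.35, and 233 were lower and 9 higher against SO-L1 (median -0.27). The median change of these genes was below 0 in each of the 4 same-number pairs of both comparisons and with each of 3 scalings. The 170 genes lower in SO-L1 than in ASO-Ctr in the blocked fit had a median span of 188 kb.

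**Figure D4:**
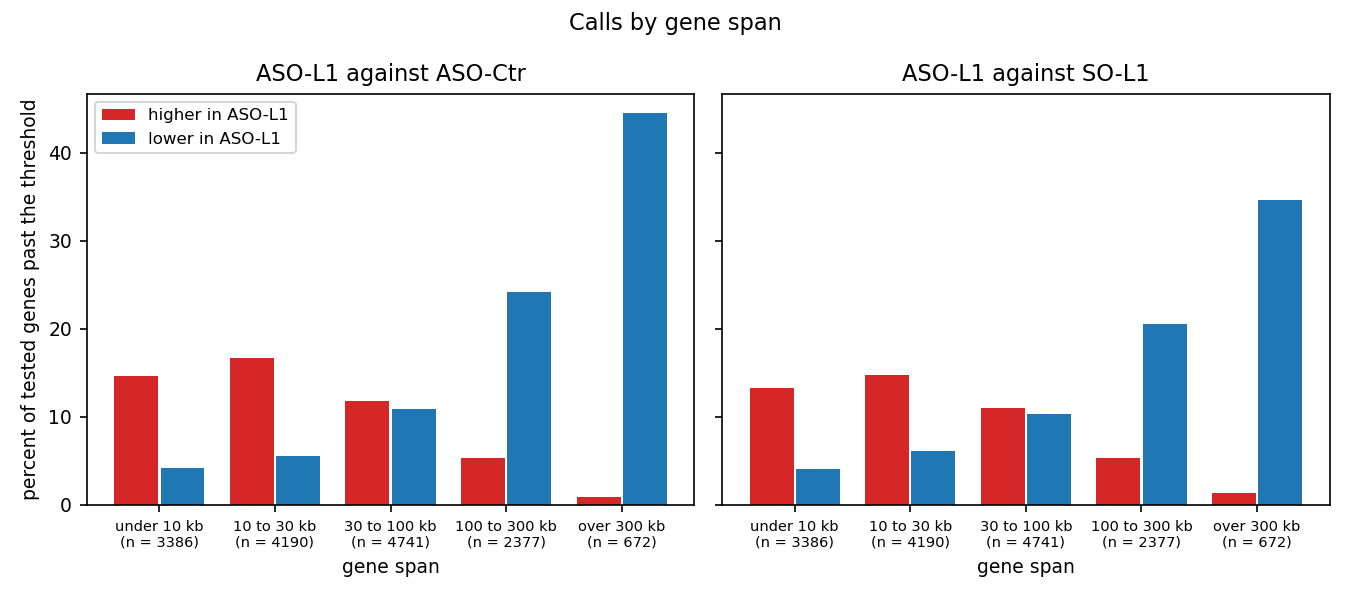
Percent of tested genes past the threshold (y axes, linear from 0) by gene span (x axes, number of genes under each bin), higher in red and lower in blue, for ASO-L1 against ASO-Ctr and against SO-L1. The lower share goes from 4.19% under 10 kb to 44.5% over 300 kb on the left, and from 4.05% to 34.7% on the right.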

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

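The tests of transfection with any L1 oligo, of a gain of short genes and of fibroblasts or feeder cells were chosen only after the result was seen, as were the fits within numbers 1 and 2 and within numbers 3 and 4.

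Genes lower in ASO-L1 than in both other groups had long spans, with a median 3.20 times that of tested genes of like expression (range of the matched draws 2.95 to 3.46). When exonic length was matched as well the ratio was 2.32 (2.17 to 2.50). That lies between the limits set beforehand, under 1.5 for a bias by mature transcript length and above 3 against it. Since it stays above 1.5 by more than its range, exonic length is argued against as the whole cause, while a part of the excess may go with it. An effect of ASO-L1 on long genes, for instance through L1 copies in their introns, stays an untested hypothesis, since no repeat annotation was used here.

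Genes lower in SO-L1 than in ASO-Ctr in the blocked fit also had long spans, 5.72 times those of matched genes (4.45 to 7.53), and 3.42 times (2.78 to 4.08) with exonic length matched. The ratio was above the limit of 3 set beforehand, though the lower end of its range was not, and the whole range was above 1.5, which argues against mature transcript length as the whole cause. Across genes over 100 kb, changes in SO-L1 and ASO-L1 against disjoint ASO-Ctr libraries reached 0.323 of the attainable correlation (0.293 to 0.349), between the limits of 0.25 and 0.5, so a shared effect of both L1 oligos cannot be told apart from separate ones.

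Of 70 tested members of the ATF4, immediate early and 8-cell stage lists, 33 were called higher in ASO-L1 than in ASO-Ctr, with a median log2 change of 1.13, and only the immediate early list kept its camera call with an estimated correlation (adjusted p = 0.00294, against 0.152 and 0.299). In SO-L1 the 33 had 0.0480 of that change, but they were picked by their rise in ASO-L1. Over all tested immediate early genes, called or not, the median changes in SO-L1 and ASO-L1 against ASO-Ctr were -0.003 and 0.68. For 8-cell stage genes they were 0.08 and 1.95. For both lists this argues against a response to any L1 oligo as the whole cause. For the 38 ATF4 genes they were 0.07 and 0.05, so for that list as a whole the test does not decide. With the block the ATF4 list was called higher in SO-L1 too by camera (adjusted p = 9.37e-04, and adjusted p = 0.617 with an estimated correlation). All 70 members, called or not, had a median of 0.45, of which genes matched on expression and span had 0.0609 (-0.0569 to 0.175), which argues against a relative gain of short genes as the whole cause. Fibroblasts or feeder cells in these unsorted cultures stay open. The median change of 4 collagens was 0.0950 of that of VIM, and TAGLN changed by 1.95. COL1A1 was higher (0.80, adjusted p = 0.0425). COL1A2 (-0.18, adjusted p = 0.272), COL5A1 (0.05, adjusted p = 0.882) and COL6A3 (0.21, adjusted p = 0.715) did not pass. COL3A1, chosen as well, was not among the tested genes. Since the collagens did not move alike, their median decides nothing. An effect of the ASO-L1 oligos, whether through L1 RNA or not, stays open too, since neither L1 RNA nor a further antisense set was measured here.

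Of the 35 splits of the 8 libraries, 1 gave as many genes as ASO-L1 against ASO-Ctr (3847, highest other 1839) and 1 as many as ASO-L1 against SO-L1 (3497, highest other 2572). In each case this was the real split, and 1 of 35 is the smallest share possible. It has a meaning as a share under 0.05 only where all splits count alike. The structure by number goes against that, so these counts alone do not exclude chance. For SO-L1 against ASO-Ctr 2 splits gave at least 5 genes, so this count alone does not exclude chance. The other of these was the split of numbers 1 and 2 from numbers 3 and 4, with 6404 genes, which points to a structure of the samples and was the highest other in each comparison; none of the remaining splits reached 5. With the block, the real splits gave 7747, 7469 and 243 genes, and in each comparison the highest other of the 8 splits that part as many pairs gave 0. For all 3 comparisons 8 splits are too few for a share under 0.05.

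The effect differed between numbers 1 and 2 and numbers 3 and 4 for 134 genes in ASO-L1 against ASO-Ctr and for 303 against SO-L1, by an interaction test. Untested 8-cell stage genes held 301 counts in ASO-L1 against 60 in ASO-Ctr and 84 in SO-L1.

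Single libraries lay far from the others of their group in 12 of 534 groups of values. About 27 would be so by chance if the 4 values of a group were independent and alike in spread. The split of the libraries by number goes against that, so nothing is drawn from 12 being below 27. ASO-Ctr 2 had 4.74% mitochondrial counts (others 7.81% to 8.08%), 4.96% of counts in its 10 highest genes (others 7.38% to 7.73%) and 1903 CPM of RPL8 (others 1656 to 1697). In SO-L1, MOBP was at 3.79 CPM in library 2 and PFKP at 176 CPM in library 1. In ASO-L1 1, ALX1 was at 4.73, IRF7 at 13.5 and DHCR7 at 88.0 CPM. NPM1 was at 1809.7 CPM in ASO-L1 3, and in ASO-L1 4 MYO6 was at 118, AURKA at 133 and MT-ND4 at 7212 CPM.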

How the results depend on the processing

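The covariate for the set of numbers and the fits within a set were chosen only after seeing the data. Counts are given in the order ASO-L1 against ASO-Ctr, ASO-L1 against SO-L1, SO-L1 against ASO-Ctr, and same way in both ASO-L1 comparisons; without a change of setting they are 3847, 3497, 5 and 2982.

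With the block they were 7747, 7469, 243 and 6270, with the block and RLE factors 7737, 7463, 240.0 and 6259, and with the set covariate 7822, 7517, 246 and 6317. Numbers 1 and 2 alone gave 6045, 5863, 124 and 4702, and numbers 3 and 4 alone 6103, 5861, 201 and 4682. The deposited log2 values in limma gave 9356, 9144, 601 and 7520. Tested against a fold of 1.5 the counts were 245, 207, 0 and 190.0, the 0 in edgeR with 14 genes at an unadjusted p under 0.05. For SO-L1 against ASO-Ctr, library sizes alone, no count filter and a CPM of at least 1 each gave 8 genes, and DESeq2 gave 46. Leaving out each library gave 3131 to 3861, 2741 to 3446, 5 to 7 and 2373 to 2743.

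Of 13 lists called in each ASO-L1 comparison, 1 and 2 were called with an estimated correlation, and for SO-L1 against ASO-Ctr 6 were called with the block instead of 0. The median of the 8-cell stage genes stayed positive in every setting where it was computed, and its camera call held in these but not with an estimated correlation (adjusted p = 0.299 and 0.265). It ran from 1.21 to 2.30 against ASO-Ctr and from 1.35 to 2.28 against SO-L1; it has no value for the fold test.

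Of 246 calls of named genes, the block kept 246 and the fold test 66. The other settings lost at most 15 of the calls they tested, the most without ASO-L1 3. With a CPM of at least 1 in at least 4 libraries only 236 of the calls were tested, and ZSCAN4 was not among them. The fold test lost the ZSCAN4 call against ASO-Ctr and kept that against SO-L1. None of the 246 calls reversed where tested. IFITM1, not called in ASO-L1 against SO-L1, went to 0.108 (adjusted p = 0.0439) in numbers 3 and 4 alone. The causes of these differences were not tested.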

Other observations

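The comparison of numbers 3 and 4 with numbers 1 and 2 was chosen only after the result was seen. Across all groups, 5081 genes were higher and 4774 lower in numbers 3 and 4. Of 34 glycolysis and hypoxia genes 33 were lower and 0 higher (median -0.84), and BHLHE40, named after its values were seen, was lower by a log2 change of -1.71. Of 73 nucleolar genes 50 were higher and 3 lower, of 80 ribosomal protein genes 6 were higher and 41 lower, and of 30 p53 targets 5 were higher and 21 lower. Of the 9 tested 8-cell stage genes 6 were higher and 1 lower (median 0.84). In ASO-L1 against ASO-Ctr, BHLHE40 changed by 0.13 in numbers 1 and 2 and by 1.55 in numbers 3 and 4 (adjusted p of the difference 1.16e-19).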
